A study of Mus musculus with 23 samples.

How the data were processed

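RNA from mouse hearts was measured by RNA sequencing in 23 libraries. Per the labels, the mice were C57BL/6, either wild type (WT) or carrying a calcineurin A transgene expressed in heart muscle cells (CnATg), and received vehicle or JIB-04, an inhibitor of Jumonji histone demethylases. The dose of JIB-04 was 50 mg/kg, given on 3 occasions in each week. Hearts were taken at day 45 (treatment from week 4) or at day 77 (treatment from week 5), so age and week of treatment start go together and cannot be told apart. The 7 groups were, at day 45, WT vehicle, WT JIB-04, CnATg vehicle and CnATg JIB-04 with 3 libraries each, and, at day 77, CnATg vehicle and CnATg JIB-04 with 4 libraries each and WT JIB-04 with 3. The description of the whole study speaks of vehicle only for WT mice, whereas the labels of single samples place WT libraries under JIB-04 at both ages. Groups followed the sample labels, the WT JIB-04 start week is not given there, and no day-77 WT vehicle group was analysed here. The labels name no batch and do not say outright that each library came from a separate mouse. Libraries were treated as independent. The WT JIB-04 samples are numbered apart from all others in the deposit, so a batch of their own cannot be excluded in comparisons that use them.

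Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an mRNA kit that does not keep strand. Reads from overlapping and antisense genes therefore cannot be told apart. Per the submitters' processing notes, STAR 2.7.1a, Picard, GATK 4.1.2 and Cufflinks 2.2.1 were used with the GRCm38 mouse genome; what each step did, the annotation and the filters are not stated. The deposited values are log2 FPKM per feature, per the file headers. The design written in advance assumed plain FPKM. The deposited log2 values had no negative entry, exact zeros and a run of small values from 0 upward, so they were read as log2(FPKM + 1), which is the scale that design called for, and were used without a further transformation. FPKM was computed back from them where levels are given.

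Each library held 43154 features, in which 58 symbols occurred more than once, over 124 features. In 6 files 1 blank line was dropped. Of the features, 39344 had a symbol of the GENCODE M21 annotation, and 30414 had the same locus in it after 1 was added to the starts, so positions are given 1-based on GRCm38. The mitochondrial transcripts mt-Atp6, mt-Atp8 and mt-Co3 were listed at 0 in 13 libraries and near the top of the range in the other 10, and were left out as failed estimates. Acta1, Cox4i1, Slc7a5 and Map1lc3b were not analysed here.

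Read counts and absolute depth are unknown, so no counting error or detection limit could be given, and precision rests on the spread between libraries. Relative depth was read from the smallest steps of the values, 1 fragment in genes of low expression with a locus of 900 to 4000 bases. It ran from 0.589 to 1.321 of the mean library. Libraries with more Ddx3y than Xist, 9 of the 23, were taken as male, and both sexes occurred in every group.

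Comparisons were made with limma 3.58.1 in R 4.3.3 (linear model by group, empirical Bayes with an intensity trend, two-sided moderated test, Benjamini-Hochberg adjustment), over features with an FPKM of at least 1 in at least 3 libraries of the fit, at an adjusted p under 0.05. Each fit held all libraries of an age, 12 at day 45 and 11 at day 77, and all 23 where ages were compared. There were 9 comparisons. Replicate numbers were not used as a block. The 39 gene lists of heart, metabolic, stress, signalling, cell-type and RNA-quality genes were tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Camera asks whether a list moved relative to other genes. Benjamini-Hochberg adjustment ran over the lists of a comparison, and list members were counted over all genes and adjusted over the list alone. Correlations of effects are across genes, which are not independent replicates. Where the effects shared libraries, 100 simulated draws of unchanged groups, from residuals of all 12 day-45 libraries, estimated the value that sharing alone produces. The residual variance gave a second estimate of that value.

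The comparisons, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule took, for the 3 main comparisons, up to 12 genes each way with the largest log2 fold change among genes past the threshold whose libraries did not overlap between groups, with a mean FPKM of at least 2 in the higher group, leaving out gene models named Gm, Rik, BC or AC, pseudogenes, Xist and Y-linked genes, and up to 5 each way for the other comparisons. Members of a list, Ppp3ca, Rcan1 and Jumonji demethylase genes could be named besides. The list members shown as examples were chosen after their values were seen, and 4 candidate examples (C1qa and Cpt1b in the genotype effect, Col1a1 in the JIB-04 effect in WT, Postn in the day-77 JIB-04 effect) were dropped after their sign turned under a rescaling. Gm11382 was named after its values were seen, because it alone passed the threshold in a comparison.

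Each result was recomputed with a pseudocount of 0.1, without the low-value filter, with a mean FPKM of at least 5, after median-ratio scaling, after quantile normalization, with mitochondrial and hemoglobin genes left out and the rest rescaled, with only the groups compared, with all libraries together, without the intensity trend, with array weights, with the replicate number as a block, with sex as a covariate, and without each library of the groups compared. Features under 300 bases left out, the library WT JIB-04 day 45 replicate 2 left out, and some list and correlation settings were added after seeing the data.

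The code was tested on simulated data with 200 altered genes, 50 at each log2 size. For the day-45 genotype effect (13008 genes), 5 of the 50 genes at a size of 0.25, 24 at 0.5, 45 at 1 and 48 at 2 were recovered, with 12 false calls among 134. For the day-45 JIB-04 effect in CnATg (13010 genes), the numbers were 7, 25, 49 and 50, with 5 false calls among 136. For the day-77 JIB-04 effect (12971 genes), they were 3, 31, 47 and 50, with 5 false calls among 136. The difference between ages (13378 genes) gave 6, 20, 41 and 48, and the day-45 interaction (13006 genes) gave 2, 20, 45 and 47. Camera found 5 of 5 shifted lists and called 1 of 15 unshifted ones. The simulated genes varied independently of each other, so this says nothing about false calls for lists whose genes vary together. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.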

Results

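Gene expression was measured in 23 mouse heart libraries, 14 from CnATg mice, which carry a calcineurin A transgene in heart muscle cells, and 9 from WT mice. Calcineurin is a calcium-activated phosphatase that acts through NFAT transcription factors and drives hypertrophic growth of the heart, and JIB-04 inhibits Jumonji histone demethylases. The study asked what this inhibition does to gene expression in the hypertrophic heart. Between 12384 and 12782 features per library had an FPKM of at least 1. The mitochondrial share of the summed FPKM was 15.5 to 17.4% in CnATg and 20.8 to 27.1% in WT libraries. Relative depth was 0.967 to 1.32 in CnATg and 0.589 to 0.957 in WT. These ranges did not overlap, but the gap from 0.957 to 0.967 is narrow and the error of the depth estimate is unknown. The lowest WT values of both measures came from WT JIB-04 day 45 replicate 2; without that library WT ran from 24.1 to 27.1% and from 0.842 to 0.957.

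Ppp3ca, which encodes the calcineurin A alpha subunit (chromosome 3, 136670124 to 136937727), separated the genotypes in every library. It lay at 1415 to 1987 FPKM in the 14 CnATg libraries and at 23.6 to 29.0 FPKM in the 9 WT libraries. Reads of a transgene count there only as far as they match the mouse gene. Rcan1, a gene that calcineurin switches on, averaged 79.2 ± 13.045 FPKM (SD, n = 3) in CnATg with vehicle and 25.2 ± 0.902 FPKM (n = 3) in WT with vehicle at day 45. With JIB-04, Rcan1 averaged 78.1 ± 10.5 FPKM in CnATg at day 45 (n = 3) and 86.0 ± 13.8 at day 77 (n = 4), beside 84.9 ± 19.9 with vehicle at day 77 (n = 4).

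The genotype effect at day 45 asked what the transgene did to the heart without drug. Muscle genes were among those that changed most. Myh7, the slow beta myosin heavy chain (chromosome 14, 54970688 to 54994634), averaged 1659 ± 25.1 FPKM in CnATg and 82.5 ± 11.965 FPKM in WT (SD, n = 3 each; log2 fold change 4.32, SE 0.10). Tpm2, a tropomyosin of slow muscle (chromosome 4, 43514711 to 43523765), averaged 778 ± 19.5 against 12.1 ± 0.445 FPKM (log2 5.89, SE 0.05). Myom2, an M-band protein of the mature sarcomere (chromosome 8, 15057653 to 15133541), fell from 264 ± 23.8 to 11.6 ± 2.77 FPKM (log2 -4.42, SE 0.14).

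By the naming rule, the largest increases after Ppp3ca and Tpm2 were Igsf23 (log2 5.48), the phosphatase inhibitor Ppp1r1c (5.26), the muscle hormone Ostn (5.21), Leprel1, now named P3h2 (4.80), the Wnt antagonist Dkk2 (4.73), Myh7, Edn3 (4.26), the Wnt receptor Ror2 (4.25), Sprr1a (3.91) and Dct (3.84). Several of these, such as Ostn, Dkk2 and Ppp1r1c, had WT means far under 1 FPKM, where the added 1 FPKM holds the log2 value down. Among the largest decreases after Myom2 were the lipase Ces1d (-3.90), Pla2g5 (-3.26), the potassium channel subunit Kcne1 (-3.26), Lrrc4b (-3.19), Epn3 (-3.19), Phkg1 (-3.07), Lrrc15 (-3.02), Pde1c (-2.94), Fbp2 (-2.91) and Lypd2 (-2.53). In all, 5213 of 13289 genes passed limma's adjusted threshold, 3100 higher and 2113 lower, and 736 of them changed at least 2-fold. The libraries of the groups did not overlap for 49.6% of genes, where chance gives 10%. The split between directions depended on scaling. With 59.5% of calls higher as deposited, the share was 48.0% after median-ratio scaling, 45.5% after quantile normalization and 73.6% with mitochondrial and hemoglobin genes left out and the rest rescaled.

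Of 12 fetal and hypertrophic genes, 10 were higher and 0 lower over all genes, 11 and 0 adjusted over the list alone. Nppa averaged 749.6 ± 206 against 231 ± 56.6 FPKM, Nppb 628 ± 69.7 against 151 ± 83.0 FPKM, and Nmrk2 (log2 3.22) and Fhl1 (2.07) rose as well. The list's camera adjusted p was 6.6e-07, and adjusted p = 0.15 with an estimated correlation. Contractile genes of the mature heart went both ways, 5 higher and 8 lower of 17 (6 and 8 adjusted over the list alone). Ldb3 (0.76) and Actn2 (0.52) were higher, while Tnni3 (-0.42) and Myh6 (-0.36) were lower, both to a level no longer past the threshold after quantile normalization. Myh6 and Myh7 are near-identical copies, so reads may be split between them. Calcium-handling and ion-channel genes were 6 higher and 11 lower of 23 on either adjustment, with Hcn2 (-2.04), Kcnj3 (-1.08) and Pln (-0.44) lower and Kcnip2 (1.18) and Jph2 (0.76) higher. That list's camera adjusted p was 0.037, and adjusted p = 0.53 with an estimated correlation. It rose to 0.051, 0.067, 0.13 and 0.060 without CnATg vehicle replicate 1, CnATg vehicle replicate 3, WT vehicle replicate 2 and WT vehicle replicate 3, and to 0.078 after median-ratio scaling. Of 13 calcineurin and NFAT genes, 4 were higher and 3 lower on either adjustment (Ppp3ca itself, Rcan1 1.60, Rcan2 0.77 and Gata4 0.61 higher; Nfatc2 -0.46, Nfatc4 -0.26 and Myoz2 -0.13 lower), with a list median of 0.06 that turned to -0.01 after median-ratio scaling and -0.04 after quantile normalization. Nfatc4 and Myoz2 passed narrowly, and neither passed over all genes without CnATg vehicle replicates 1, 2 or 3 (adjusted p 0.055, 0.098 and 0.11 for Nfatc4, 0.18, 0.072 and 0.057 for Myoz2), WT vehicle replicate 1 (0.096 and 0.13) or WT vehicle replicate 2 (0.11 and 0.086), or with mitochondrial and hemoglobin genes left out.

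Of 31 genes of oxidative phosphorylation and the citric acid cycle, 1 was higher and 26 lower over all genes, 1 and 27 adjusted over the list alone. Citrate synthase Cs fell from 480 ± 9.85 to 304 ± 6.65 FPKM (log2 -0.66) and Cox7a1 fell by 0.81 on the log2 scale. The list's camera adjusted p was 2.8e-13, and adjusted p = 0.19 with an estimated correlation. Fatty-acid oxidation genes were 2 higher and 14 lower of 26 on either adjustment, among them Eci1 (-0.88), Hadh (-0.60) and Acadvl (-0.56). The camera adjusted p was 5.4e-05, and adjusted p = 0.53 with an estimated correlation. Glycolysis genes were 5 higher and 10 lower of 19 on either adjustment, with Gpi1 (1.71) and Hk1 (1.07) higher and Pfkp (-1.41), Ldha (-0.98) and Eno3 (-0.92) lower. Its camera adjusted p of 0.037 became adjusted p = 0.53 with an estimated correlation, and 0.058, 0.058 and 0.064 without CnATg vehicle replicate 1, CnATg vehicle replicate 3 and WT vehicle replicate 2. All 7 mitochondrially encoded transcripts tested were lower on either adjustment (camera adjusted p 5.7e-06, and adjusted p = 0.15 with an estimated correlation). Among them mt-Nd1 averaged 3766 ± 237 against 6170 ± 234 FPKM, a decrease no longer past the threshold after quantile normalization.

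Matrix and fibrosis genes rose, 31 higher and 1 lower of 41 over all genes, 33 and 2 adjusted over the list alone. The growth factor Tgfb3 averaged 93.4 ± 15.6 against 5.77 ± 0.554 FPKM (SD, n = 3 each), Ctgf 203 ± 27.5 against 21.01 ± 3.78 FPKM and Col1a1 59.2 ± 1.23 against 19.1 ± 1.82 FPKM. Spp1 (log2 3.35), Timp1 (3.02), Cilp (2.83) and Postn (1.29) rose too, and the basement-membrane gene Col4a1 fell by 0.49. The list's camera adjusted p was 3.2e-09, and adjusted p = 0.34 with an estimated correlation. Fibroblast markers were 7 higher and 1 lower of 10 (8 and 1 adjusted over the list alone), with Mfap5 at 1.14 and Clec3b at -0.97. Endothelial markers were 0 higher and 12 lower of 12 on either adjustment. Cdh5 fell from 60.4 ± 2.62 to 28.4 ± 2.12 FPKM and Pecam1 fell by 0.77 (camera adjusted p 5.2e-09, and adjusted p = 0.15 with an estimated correlation). Interferon-response genes were 0 higher and 15 lower of 22 (0 and 17 adjusted over the list alone), among them Rsad2 (-1.25). Their camera adjusted p was 5.7e-06, and adjusted p = 0.53 with an estimated correlation. Atrophy and ubiquitin-ligase genes were 10 higher and 1 lower of 12 on either adjustment, with Bdnf (1.96), Fbxo32 (0.94) and Foxo3 (0.90) higher (camera adjusted p 0.0050, and adjusted p = 0.34 with an estimated correlation).

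**Figure D1:**
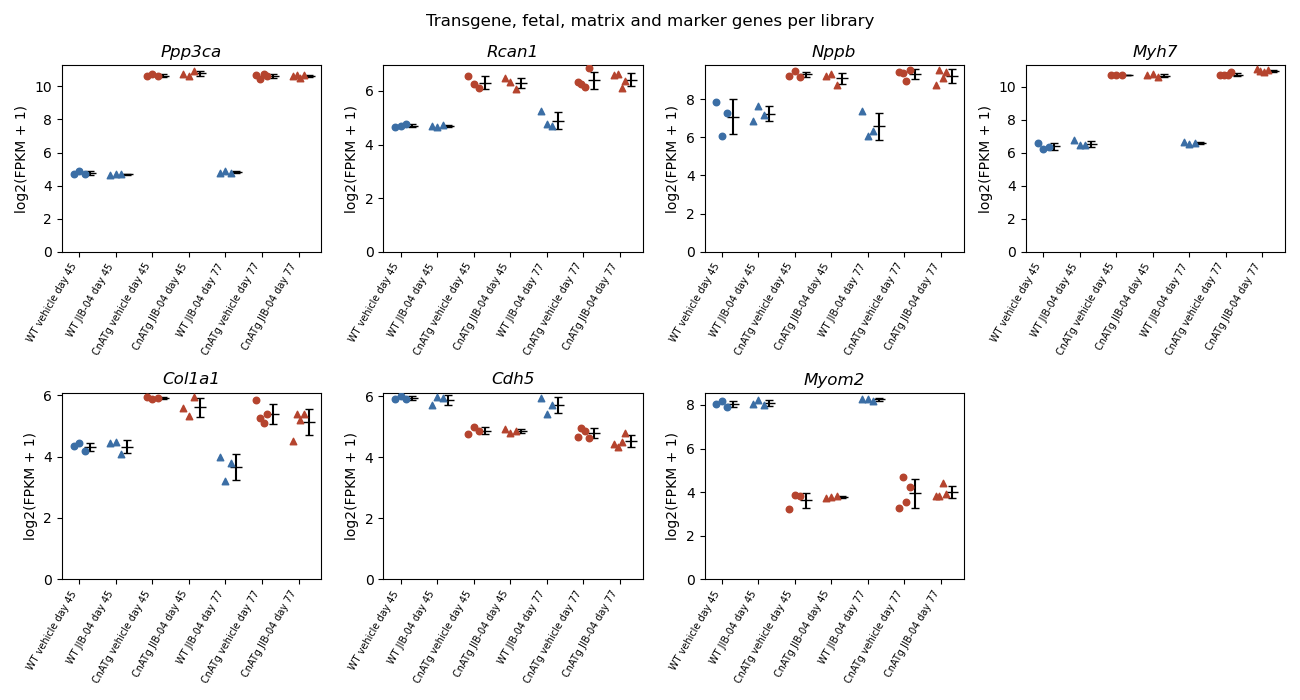
Expression as log2(FPKM + 1) of 7 genes in each library, by group, in blue for WT and red for CnATg, circles for vehicle and triangles for JIB-04, with the mean (dash) and SD (bar) beside the points. Ppp3ca, Rcan1, Nppb, Myh7 and Col1a1 lay higher in CnATg groups, and Cdh5 and Myom2 lay lower.

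Under JIB-04 at day 45, CnATg hearts were set against WT hearts that also received the drug. Genes named above stood out there as well, with Ppp3ca (log2 6.12), Tpm2 (5.93), Igsf23 (5.28), Ppp1r1c (4.94) and Leprel1 (4.89) the largest increases and Myom2 (-4.32), Ces1d (-4.00), Pla2g5 (-3.28), Phkg1 (-3.18) and Pde1c (-3.08) the largest decreases by the naming rule (n = 3 each). Nppa rose by 1.35, Nppb by 1.85, Rcan1 by 1.60, Ctgf by 2.73 and Tgfb3 by 3.72, while Cdh5 (-1.02) and Cs (-0.69) fell. Fetal genes were 9 higher and 0 lower of 12 over all genes and adjusted over the list alone, and matrix genes 29 and 1 of 41 (31 and 1 adjusted over the list alone). Genes of oxidative phosphorylation were 0 higher and 28 lower of 31 on either adjustment, and endothelial markers 0 and 11 of 12 (0 and 12 adjusted over the list alone). These lists had camera adjusted p of 2.0e-06, 3.1e-09, 4.1e-14 and 2.1e-07, and adjusted p = 0.20, 0.39, 0.20 and 0.20 with an estimated correlation. In all, 5128 genes passed limma's threshold, 2728 higher and 2400 lower, a share of 53.2% higher that became 50.3% after median-ratio scaling, 48.6% after quantile normalization and 83.5% with mitochondrial and hemoglobin genes left out. Across 13289 genes this effect correlated with the vehicle genotype effect (r 0.885, rho 0.840), with which it shares no library. Of the genes called, 2295 were higher in both comparisons, where independent lists would share 636, and 1810 were lower in both, where they would share 382.

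CnATg hearts with JIB-04 against WT hearts with vehicle asked how far treated transgenic hearts still differed from the untreated normal heart. The genes standing farthest apart were Ppp3ca (6.03), Tpm2 (5.89), Igsf23 (5.47), Ppp1r1c (4.97) and Leprel1 (4.89) upward and Myom2 (-4.28), Ces1d (-3.74), Lrrc4b (-3.15), Pla2g5 (-3.10) and Kcne1 (-3.08) downward. Fetal genes were 9 higher and 0 lower of 12 (10 and 0 adjusted over the list alone), matrix genes 28 and 2 of 41 (30 and 2 adjusted over the list alone), and interferon-response genes 0 and 16 of 22 (0 and 18 adjusted over the list alone). Their camera adjusted p were 6.4e-07, 1.1e-07 and 5.6e-06, and adjusted p = 0.22, 0.39 and 0.56 with an estimated correlation. Cell markers moved with them. Endothelial markers were 0 higher and 11 lower of 12 (0 and 12 adjusted over the list alone; camera adjusted p 9.9e-08), B-cell genes 0 and 3 of 5 (0.029, and 0.080 without WT vehicle replicate 3) and mitochondrially encoded transcripts 0 and 7 of 7 (5.8e-05), with adjusted p = 0.22, 0.39 and 0.25 with an estimated correlation. Fibroblast markers were 7 higher and 1 lower of 10 (8 and 1 adjusted over the list alone; camera adjusted p 0.058). Limma called 5031 genes, 2672 higher and 2359 lower, so that 53.1% were higher, or 49.1% after median-ratio scaling, 45.8% after quantile normalization and 70.1% with mitochondrial and hemoglobin genes left out.

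The JIB-04 effect in CnATg hearts at day 45 asked whether the drug moved the hypertrophic program. Myh7 averaged 1628 ± 76.8 FPKM with JIB-04 and 1659 ± 25.1 FPKM with vehicle (SD, n = 3 each), and its log2 difference of -0.03 had a 95% interval of -0.26 to 0.20. For Nppa the difference was 0.06 (-0.57 to 0.70), for Nppb -0.21 (-1.004 to 0.59), for Ppp3ca 0.13 (-0.05 to 0.32) and for Rcan1 -0.02, the last turning to 0.03 after median-ratio scaling. Without 1 library the value for Ppp3ca ran from 0.05 to 0.21. The intervals of Nppb and Nppa leave room for sizeable effects, and Nppb fell to -0.04 without CnATg JIB-04 replicate 3. Of 13289 genes, 1 passed limma's threshold. It was Gm11382, a pseudogene of 168 bases (chromosome 13, 32938524 to 32938691), at 36.1, 54.3 and 29.8 FPKM in the vehicle libraries and listed at 0 in the JIB-04 libraries. Without any 1 of the 3 vehicle libraries Gm11382 no longer met the low-value filter and was not tested. The number called was then 0 without CnATg vehicle replicate 1 or replicate 3, and 1, another gene, without CnATg vehicle replicate 2. At an unadjusted p under 0.05 there were 585 genes, where chance gives 664. The 95% interval of a typical gene reached 0.22 to either side on the log2 scale.

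Some groups of genes leaned together by small amounts in that comparison, with 0 members past the threshold over all genes. Fatty-acid oxidation genes were higher in 26 of 26 members (median 0.10, camera adjusted p 5.2e-10, and adjusted p = 0.41 with an estimated correlation), for example Acot2 at 0.41. Contractile genes were higher in 17 of 17 members (median 0.05, adjusted p 2.5e-04, and adjusted p = 0.41 with an estimated correlation), and their adjusted p was 0.077 without CnATg vehicle replicate 3. Matrix genes were lower in 39 of 41 members (median -0.17, adjusted p 1.4e-04, and adjusted p = 0.48 with an estimated correlation), for example Col1a1 at -0.30 (-0.61 to 0.01), Postn at -0.44 and Col3a1 at -0.31. Without CnATg JIB-04 replicate 2 the matrix median was -0.05 and the adjusted p 0.95, Postn was at -0.05, Col3a1 at -0.12, Col1a1 at -0.15 and Acot2 at 0.26. Cell-cycle genes were lower in 17 of 18 members (median -0.15, adjusted p 0.0028, and adjusted p = 0.41 with an estimated correlation). Of those, Birc5 (-0.63) and Mcm5 (-0.45) were lower adjusted over the list alone, both at a list adjusted p of 0.020, and the camera adjusted p of the list was 0.061 without CnATg JIB-04 replicate 2. Glycolysis genes were lower in 18 of 19 members (median -0.06, adjusted p 0.015, and adjusted p = 0.41 with an estimated correlation), and their adjusted p was 0.13, 0.064 and 0.31 without CnATg JIB-04 replicate 2, CnATg JIB-04 replicate 3 and CnATg vehicle replicate 2, and 0.18 after median-ratio scaling. Camera called 5 more lists, all upward. They were erythroid genes (6 of 6 higher, median 0.59, adjusted p 3.7e-05), smooth muscle and pericyte markers (7 of 9, 0.10, adjusted p 0.0038), clock genes (9 of 13, 0.05, adjusted p 0.024), mitochondrially encoded transcripts (5 of 7, 0.09, adjusted p 0.035) and NRF2 targets (10 of 18, 0.02, adjusted p 0.035), with adjusted p = 0.41, 0.24, 0.41, 0.41 and 0.48 with an estimated correlation. The erythroid call was lost without CnATg JIB-04 replicate 1 (0.10), the clock call without CnATg JIB-04 replicate 1 (0.16) or CnATg vehicle replicate 2 (0.24), and the mitochondrial call without CnATg JIB-04 replicate 3 (0.37), CnATg vehicle replicate 1 (0.11) or CnATg vehicle replicate 3 (0.25). That of NRF2 targets was lost, with a median turned below 0, without CnATg JIB-04 replicate 1 (0.88), CnATg JIB-04 replicate 2 (0.083) or CnATg vehicle replicate 3 (0.76). Fetal genes had a median of -0.06 (camera adjusted p 0.41), and Nmrk2 (-0.57) alone was lower adjusted over the list alone. Camera called 10 lists here and 0 with an estimated correlation, and fry called 0. Other splits of the same 6 libraries gave up to 11.

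In WT hearts at day 45, JIB-04 against vehicle asked what the drug did in the normal heart. Nppa differed by 0.40 on the log2 scale (95% interval -0.23 to 1.03, n = 3 each), Myh7 by 0.17, Nppb by 0.17 and Acaa2 by 0.18. Without 1 library the value for Nppa ran from 0.28 to 0.61. That for Nppb turned to -0.004 with array weights and to -0.04 and -0.33 without WT JIB-04 replicate 2 and WT vehicle replicate 2. That for Myh7 fell to 0.06 and 0.08 without WT JIB-04 replicate 1 and WT vehicle replicate 2. Limma called 0 of 13289 genes, with 576 at an unadjusted p under 0.05 where chance gives 664, and 1 gene without WT JIB-04 replicate 1 or without WT vehicle replicate 2. Fatty-acid oxidation genes were higher in 25 of 26 members (median 0.12, camera adjusted p 6.1e-09, and adjusted p = 0.84 with an estimated correlation) and oxidative phosphorylation genes in 30 of 31 (median 0.06, adjusted p 1.1e-07, and adjusted p = 0.84 with an estimated correlation). With mitochondrial and hemoglobin genes left out and the rest rescaled, the median of all genes moved by -0.115 and both lists turned, to -0.01 and -0.08. The latter was at -0.04 after quantile normalization. The rescaling depends on the summed FPKM of the genes that remain. The sum with mitochondrial and hemoglobin genes still in it was 852690 in WT JIB-04 replicate 2 beside 704090 and 736180 in replicates 1 and 3. How far that library set the turn was not tested. Metal-homeostasis genes were higher in 9 of 13 (median 0.09, adjusted p 0.049, and adjusted p = 0.84 with an estimated correlation), a call lost without WT JIB-04 replicate 1 (0.15), WT JIB-04 replicate 3 (0.074) or WT vehicle replicate 3 (0.31). The interaction, the JIB-04 effect in CnATg minus that in WT, passed limma's threshold for 1 gene, Gm11382 again. It was listed at 0 in all WT libraries, and 498 genes reached an unadjusted p under 0.05 where chance gives 664. Without any 1 of the 3 CnATg vehicle libraries the interaction count was 0, and without WT vehicle replicate 1 or 2 it was 2.

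Whether JIB-04 moved expression back toward WT was asked across genes. Over 13289 genes at day 45, the JIB-04 effect in CnATg and the genotype effect had r of -0.149 and rho of -0.172. Both effects use the CnATg vehicle libraries, which alone gives a negative value. Their covariance was -0.0145, where 100 simulated draws without any effect averaged -0.0223 (SD 0.0106), and 74 of the draws lay as low. A second estimate of the value from sharing alone, taken from the residual variance, was -0.0151, close to the observed one. The draws used residuals of all day-45 libraries, but only the CnATg vehicle libraries are shared. They therefore set no exact level for sharing alone, and no direction is read from this covariance. Of the 5213 genes called for genotype, 61.0% had a JIB-04 effect of opposite sign. The simulation gave 68.2%, but over all genes and without a genotype effect, so it sets no chance level for the called genes. The day-45 JIB-04 effect in CnATg and the day-77 genotype effect under JIB-04 share no library. Their r was -0.0429, and -0.0722 to -0.0066 without 1 library, with opposite signs for 49.1% of 5499 genes. The JIB-04 effect at day 77 and the day-45 genotype effect shared no library and had r of 0.148 and rho of 0.159, with opposite signs for 43.3% of 5129 genes. Without 1 library that r ran from 0.0958 to 0.180. The JIB-04 effects at both ages in CnATg correlated at r 0.0753 and rho 0.155, and r turned to -0.0615 over genes with a mean FPKM of at least 5. It was 0.0158 and 0.0179 without CnATg JIB-04 day 45 replicate 2 and CnATg JIB-04 day 77 replicate 1, so no direction is claimed. The JIB-04 effects in both genotypes at day 45 correlated at r 0.182 (0.111 to 0.238 without 1 library) and rho 0.0502.

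In CnATg hearts at day 77, JIB-04 against vehicle asked about a longer treatment. The interferon-response genes were lower in 21 of 22 members. Their mean per library was 2.18 ± 0.219 with JIB-04 and 2.65 ± 0.185 with vehicle on the log2(FPKM + 1) scale (SD, n = 4 each), a difference of -0.47 (exact permutation p = 0.0286, two-sided, the smallest these groups allow, and 0.314 adjusted over the lists). Vehicle replicate 2 stood apart at 2.93, beside 2.53 to 2.58 in the other vehicle libraries, and without it the list median was -0.42 in place of -0.50. None of these genes passed limma's threshold over all genes, and 14 of 22 were lower adjusted over the list alone, among them Isg15 (-0.83), Rtp4 (-0.76), Bst2 (-0.74) and Gbp2 (-0.71). The list's camera adjusted p was 1.0e-12, and adjusted p = 0.60 with an estimated correlation. Endothelial markers were lower in 11 of 12 members (median -0.24, camera adjusted p 3.1e-04, and adjusted p = 0.60 with an estimated correlation), for example Cldn5 at -0.46 and Fabp4 at -0.33. Glucocorticoid-response genes were higher in 12 of 12 (median 0.25, adjusted p 3.1e-04, and adjusted p = 0.60 with an estimated correlation), with Klf9 at 0.24. Their mean per library ran from 3.97 to 4.97 with JIB-04, on both sides of the 4.05 to 4.34 with vehicle (exact permutation p = 0.2). Fkbp5 ran from 0.24 to 0.97 without 1 library. Cell-cycle genes were lower in 13 of 16 (median -0.25, adjusted p 0.0039, and adjusted p = 0.60 with an estimated correlation), with Top2a at -0.59 and Mcm6 at -0.36, and their adjusted p was 0.066 without CnATg vehicle replicate 2. Jumonji demethylase genes were higher in 17 of 20 (median 0.05, adjusted p 0.016, and adjusted p = 0.405 with an estimated correlation), with Jmjd1c at 0.16 and Kdm8 at -0.18 (-0.10 without CnATg vehicle replicate 3), and their adjusted p was 0.10 without CnATg JIB-04 replicate 4 and 0.064 without CnATg vehicle replicate 2. Atrophy and ubiquitin-ligase genes were higher in 11 of 12 (median 0.10, adjusted p 0.0047, and adjusted p = 0.60 with an estimated correlation; 0.064 without CnATg vehicle replicate 2). Glycolysis genes were lower in 16 of 19 (median -0.08, adjusted p 0.016, and adjusted p = 0.60 with an estimated correlation; 0.25 and 0.082 without CnATg vehicle replicates 1 and 3, and 0.15 after median-ratio scaling).

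Of the genes that mark hypertrophy and fibrosis, Nppa differed at day 77 by 0.49 (95% interval -0.14 to 1.12), Nppb by -0.11 and Col1a1 by -0.27. Each leaned on single libraries: Nppa was at 0.31 and 0.17 without CnATg JIB-04 replicate 2 and CnATg vehicle replicate 3, Col1a1 at -0.06 and -0.12 without CnATg JIB-04 replicate 1 and CnATg vehicle replicate 1, and Nppb turned to 0.04 without CnATg JIB-04 replicate 1. Ppp3ca averaged 1592 ± 88.7 FPKM with JIB-04 and 1597 ± 133 FPKM with vehicle, a difference whose sign turned after median-ratio scaling. Myh7 averaged 1993 ± 96.8 FPKM with JIB-04 and 1702 ± 116 FPKM with vehicle (log2 0.23), which passed only when adjusted over the list alone. The fetal list had a median of -0.02 with 6 of 12 members on either side, and it turned to 0.03 after median-ratio scaling. Matrix genes had a median of -0.05 (camera adjusted p 0.61). Limma called 0 of 13212 genes, with a smallest adjusted p of 0.536 and 984 genes at an unadjusted p under 0.05, where chance gives 661 on average and other splits of the same 8 libraries gave up to 944. Groups did not overlap for 4.93% of genes, where chance gives 2.86% on average. Genes are not independent of each other, so neither number is a test of an excess. A typical 95% interval reached 0.21 to either side. Camera called 7 lists and 0 with an estimated correlation, fry called 0, and other splits of the same 8 libraries gave up to 12.

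**Figure D2:**
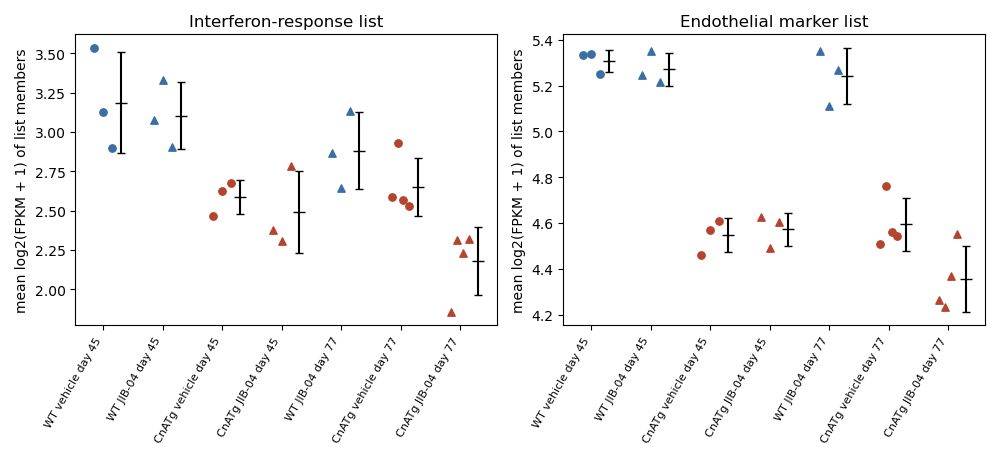
Mean log2(FPKM + 1) of the interferon-response list and of the endothelial marker list in each library by group, in blue for WT and red for CnATg, circles for vehicle and triangles for JIB-04, with group mean (dash) and SD (bar). The interferon mean was 2.18 in CnATg with JIB-04 at day 77 and 2.65 with vehicle, and both lists lay higher in WT groups.

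Under JIB-04 at day 77, CnATg hearts (n = 4) were set against WT hearts (n = 3), which asked whether the genotype effect was there at the later age. Ppp3ca (log2 5.82), Tpm2 (5.78), Dkk2 (5.25), Ostn (5.11) and Ppp1r1c (5.05) were the largest increases, and Myom2 (-4.25), Ces1d (-4.15), Pla2g5 (-3.25), Pde1c (-3.24) and Phkg1 (-3.16) the largest decreases. Nppa (1.88), Nppb (2.64), Rcan1 (1.53), Ctgf (2.90) and Tgfb3 (3.83) rose, and Cdh5 (-1.17), Rsad2 (-1.33) and Cs (-0.84) fell. Fetal genes were 10 higher and 0 lower of 12 (11 and 0 adjusted over the list alone) and matrix genes 29 and 1 of 40 (34 and 1 adjusted over the list alone). Genes of oxidative phosphorylation were 0 higher and 30 lower of 31 on either adjustment, fatty-acid oxidation genes 0 and 19 of 26 (1 and 20 adjusted over the list alone) and interferon genes 0 and 17 of 22 (0 and 20 adjusted over the list alone). The 5 lists had camera adjusted p of 8.9e-08, 1.1e-10, 6.2e-15, 5.1e-07 and 7.5e-05, and adjusted p = 0.37, 0.49, 0.49, 0.70 and 0.72 with an estimated correlation. Endothelial markers were 0 higher and 11 lower of 12 (0 and 12 adjusted over the list alone; camera adjusted p 2.0e-06, and adjusted p = 0.37 with an estimated correlation). Limma called 5557 of 13212 genes, 2635 higher and 2922 lower, with 47.4% higher, or 50.3% after median-ratio scaling, 47.9% after quantile normalization and 77.8% with mitochondrial and hemoglobin genes left out. Across 12989 genes this effect correlated with the day-45 genotype effect in vehicle (r 0.896, rho 0.827), and no library is shared. Of the calls, 2077 were higher and 1757 lower in both, where independent lists would share 615 and 458.

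**Figure D3:**
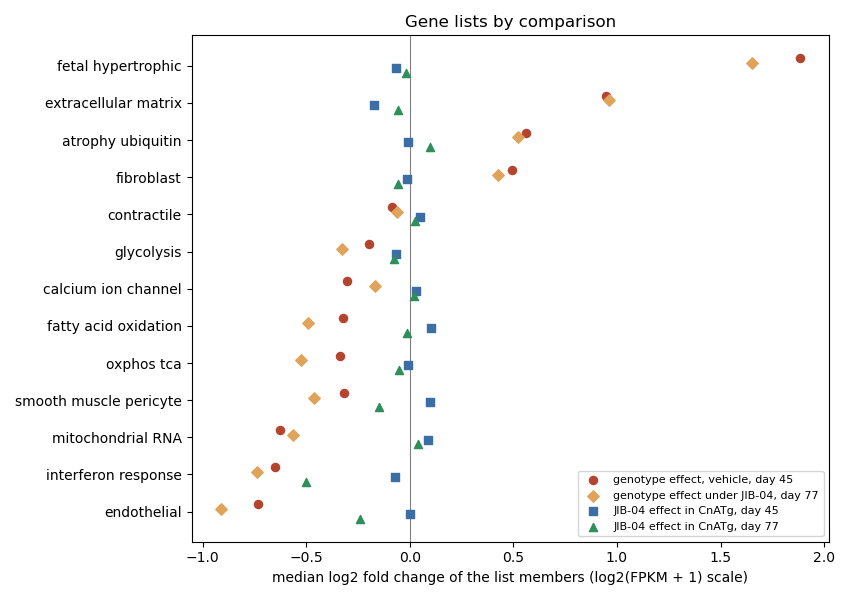
Median log2 fold change of the members of 13 gene lists in 4 comparisons, as 1 point per list and comparison. Over these 13 lists, a selection of those tested, the genotype effects spread from -0.91 to 1.88, and the JIB-04 effects in CnATg from -0.50 to 0.10. Erythroid genes at day 45 and glucocorticoid-response genes at day 77, which camera called for JIB-04, were not drawn and had higher medians.

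The difference between the JIB-04 effects at day 77 and day 45 in CnATg asked whether the drug acted differently with age and length of treatment, which the design does not separate. Limma called 0 of 13710 genes, with a smallest adjusted p of 0.451 and 464 genes at an unadjusted p under 0.05 where chance gives 686. Interferon-response genes were lower at day 77 in 21 of 22 members (median -0.36, camera adjusted p 9.0e-08, and adjusted p = 0.74 with an estimated correlation). Endothelial markers had a median difference of -0.24 (adjusted p 2.5e-05, and adjusted p = 0.31 with an estimated correlation) and fatty-acid oxidation genes one of -0.11 (adjusted p 1.1e-04, and adjusted p = 0.74 with an estimated correlation; 0.067 without CnATg JIB-04 day 45 replicate 2). Camera called 6 lists, and 10 or 11 without CnATg JIB-04 day 45 replicate 1 or CnATg JIB-04 day 77 replicate 1.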

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

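Among the tests in this part, some were chosen only after the results were seen. These were the one that took marker genes off the interferon list, its repeats without CnATg vehicle replicate 1, and the setting with features under 300 bases left out. The interferon list was itself singled out for testing because it moved.

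The interferon-response genes had a mean per library lower by 0.47 on the log2 scale with JIB-04 in CnATg hearts at day 77. Of the 35 splits of the 8 libraries, 1, the real one, gave a difference as large (-0.473, against 0.368 in size for the highest other), but the list was picked among 33 because it moved, its exact permutation p adjusted over them was 0.314, and the cell-cycle list (-0.243) and the glycolysis list (-0.078) reached the same smallest p of 0.0286, so chance is not excluded. No single library set the difference, since the list median was still -0.371 without CnATg JIB-04 replicate 1, the library that mattered most, and -0.423 without CnATg vehicle replicate 2, which stood apart on this list at 2.93 beside 2.53 to 2.58 in the other vehicle libraries. Fewer macrophages and endothelial cells remain a candidate explanation: the markers of both differed by -0.219 (exact permutation p = 0.0571), the list minus the markers by -0.254 (exact permutation p = 0.0857), and a p that misses the threshold excludes neither. The macrophage part of this leaned on 1 library, since the macrophage mean differed by -0.199 (exact permutation p = 0.229) and by -0.0687 (exact permutation p = 0.400) without CnATg vehicle replicate 1, which stood apart on it; the markers of both then differed by -0.168 and the list minus the markers by -0.328 (exact permutation p = 0.0857 and 0.0571). Other immune markers, which that test left out, were lower as well: B-cell genes by 0.318 (exact permutation p = 0.0857, and 0.471 adjusted over the lists), cytokine genes by 0.286 (exact permutation p = 0.229) and the 2 T-cell genes at a mean of 0.484 ± 0.214 with JIB-04 against 0.880 ± 0.243 with vehicle (SD, n = 4 each). An action of JIB-04 on interferon signalling stays open as an untested biological explanation, and the list was also lower in CnATg than in WT hearts in each comparison of the genotypes.

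Gm11382 passed the test of the day-45 interaction with a fitted log2 value of -5.31, which is no bound, since it was listed at 0 in CnATg with JIB-04 and in every WT library. At day 77 it was at 126 and 46.7 FPKM in CnATg JIB-04 replicates 2 and 3 and at 44.8 FPKM in CnATg vehicle replicate 4, and listed at 0 in the other 8 libraries of that age. It is a pseudogene of 168 bases, reads shared with other genes were not examined, and with features under 300 bases left out 0 genes passed.

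Between the genotypes at day 45, the JIB-04 effects differed by camera for oxidative phosphorylation genes (median -0.067, turning to 0.03 after quantile normalization and 0.08 with mitochondrial and hemoglobin genes left out; adjusted p 0.0045, and adjusted p = 0.92 with an estimated correlation). Smooth muscle and pericyte markers differed by 0.125 (adjusted p 0.029, and adjusted p = 0.44 with an estimated correlation). Erythroid genes, mostly hemoglobins whose near-identical copies can share reads, differed by 0.59 (adjusted p 0.0045, and adjusted p = 0.92 with an estimated correlation). None of these 3 calls held throughout when 1 library was left out. Adjusted p was 0.078 and 0.083 for oxidative phosphorylation without WT JIB-04 replicate 2 and WT vehicle replicate 2. For smooth muscle and pericyte markers it was 0.053, 0.054, 0.13, 0.059 and 0.093 without CnATg JIB-04 replicate 3, CnATg vehicle replicate 1, WT JIB-04 replicate 1, WT JIB-04 replicate 2 and WT vehicle replicate 2. For erythroid genes it was 0.21, 0.15, 0.086 and 0.082 without CnATg JIB-04 replicate 1, CnATg vehicle replicate 3, WT JIB-04 replicate 1 and WT vehicle replicate 2. Between the ages in CnATg, the JIB-04 effects differed by camera for fatty-acid oxidation (median -0.11), oxidative phosphorylation (-0.043, turning to 0.01 after quantile normalization), interferon response (-0.36), endothelial markers (-0.24), smooth muscle and pericyte markers (-0.24) and erythroid genes (-0.79), and for none of them with an estimated correlation. Fatty-acid oxidation lost its call without CnATg JIB-04 day 45 replicate 2 (0.067). Oxidative phosphorylation lost it without CnATg JIB-04 day 45 replicate 2 (0.083), CnATg vehicle day 45 replicate 3 (0.24), CnATg JIB-04 day 77 replicates 2 and 4 (0.19 and 0.44) and CnATg vehicle day 77 replicates 1, 3 and 4 (0.36, 0.16 and 0.074). Erythroid genes lost it without CnATg JIB-04 day 45 replicate 1 (0.42), CnATg vehicle day 45 replicate 3 (0.28), CnATg JIB-04 day 77 replicates 2 and 4 (0.13 and 0.083) and CnATg vehicle day 77 replicates 1 and 2 (0.096 and 0.33).

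In groups of 4, a single library stood apart in its list mean 4 times among 76 such cases, where chance gives about 1 in 20. The contractile mean was 9.87 in CnATg JIB-04 day 77 replicate 3 and 9.80 to 9.81 in the others of its group. The mean of AHR targets was 2.14 in CnATg JIB-04 day 77 replicate 1 and 1.94 to 1.96 in the others. The interferon mean was 2.93 in CnATg vehicle day 77 replicate 2 and 2.53 to 2.58 in the others, and the macrophage mean 3.40 in CnATg vehicle day 77 replicate 1 and 2.84 to 2.93 in the others.

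Splits of the libraries into other groups of the same sizes were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In that design the day-45 genotype effect called 5213 genes (highest other split 0), that under JIB-04 5128 (1), treated CnATg against untreated WT 5031 (1), the JIB-04 effect in CnATg 1 (3) with 10 lists (11), and that in WT 0 (1) with 3 lists (9). Splits as large, the real one included, numbered 1, 1, 1, 6, 3, 10 and 9 in that order, the 10 being fixed by a count of 0. The day-45 interaction called 1 gene, and 39 of 100 splits drawn gave as many (up to 5), so chance cannot be excluded. At day 77 the JIB-04 effect called 7 lists, and 20 of 35 splits gave as many (up to 12), so chance cannot be excluded. For the day-77 genotype effect 1 of 35 splits gave as many as 5557 genes (highest other 780), and chance can be excluded. The day-77 JIB-04 effect (other splits up to 1) and the difference between ages (up to 2) called 0 genes, which all 35 and all 100 splits reach by necessity, so those splits say nothing about chance.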

How the results depend on the processing

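The tests with features under 300 bases left out, those of the lists after median-ratio scaling and those of the correlation of genotype effects were chosen only after the results were seen. The 4 genotype comparisons kept their total counts within 1.5 times under the settings run, the day-45 vehicle effect between 3724 (mean FPKM of at least 5, where 8421 genes were tested) and 5457 (array weights). Leaving out 1 library gave 4231 to 4782 genes for that effect, 4265 to 4539 under JIB-04, 4204 to 4667 for treated CnATg against WT vehicle and 4702 to 5289 at day 77. The directions were less stable. With mitochondrial and hemoglobin genes left out, the genotype effect under JIB-04 had 5098 genes higher and 1008 lower at day 45, with 197 calls reversed, and 5434 and 1548 at day 77, with 193 reversed; the vehicle effect had 3596 and 1292 with 0 reversed, and treated CnATg against WT vehicle 3199 and 1363 with 1 reversed. After quantile normalization 10 calls of the vehicle effect, 18 under JIB-04 at day 45, 18 at day 77 and 10 for treated CnATg reversed. Taken over all groups, the library numbers showed no pairing: at day 45, 3 of 18 same-numbered pairs correlated above 0.1 and 6 of 36 others did, and at day 77 0 of 10 and 4 of 30. Between WT JIB-04 and WT vehicle at day 45, though, 2 of 3 same-numbered pairs did (0.0520 to 0.237). Differently numbered pairs there lay between -0.220 and -0.0061, so pairing in that comparison is not excluded. With the replicate block, counts were (in the order day-45 genotype, JIB-04 in CnATg, JIB-04 in WT, interaction, genotype under JIB-04, treated CnATg against WT vehicle, day-77 JIB-04, day-77 genotype, difference between ages) 5082, 1, 0, 1, 4996, 4930, 0, 4887 and 0, and no gene call count moved by over 1.5 times. Read depth is unknown. In the simulated data 7 and 3 of 50 genes at a log2 size of 0.25 were recovered for the JIB-04 effects at day 45 and day 77, and 25 and 31 of 50 at 0.5, so effects of these sizes can be missed.

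Without the low-value filter, where low values enter, the counts were 3 for the day-45 JIB-04 effect in CnATg, 2 in WT, 5 for the interaction, 3 at day 77 and 3 for the difference between ages. With all 23 libraries together the day-45 JIB-04 effect in CnATg and the interaction called 0 genes each. For the JIB-04 effect in CnATg, Gm11382 was still tested there and no longer passed. That fit also held the day-77 libraries, where Gm11382 ran from 0 to 126 FPKM within CnATg JIB-04. The part this played was not tested. With features under 300 bases left out, the JIB-04 effect in CnATg and the interaction both called 0, because Gm11382 was removed. Leaving out 1 library gave 0 to 1 genes for the day-45 JIB-04 effect in CnATg and in WT, 0 to 2 for the interaction, 0 at day 77 and 0 for the difference between ages.

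With an estimated correlation camera called 0 lists in each of the 9 comparisons. Fry, which asks whether a list's genes move one way on balance, called 19, 0, 0, 0, 21, 19, 0, 18 and 0 lists in that order. After median-ratio scaling the interaction had 0 lists. Without 1 library, lists numbered 2 to 6 for the JIB-04 effect in WT (6 without WT JIB-04 replicate 2), 0 to 7 for the interaction (0 without WT vehicle replicate 2) and 4 to 11 for the difference between ages; the cause was not tested.

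Several small JIB-04 effects changed sign. Median-ratio scaling moved the median of all genes by 0.0399 at day 45 and 0.0395 at day 77 in CnATg, about as much as it moved the genes that turned under it, so these turns reflect a shift of all genes; the cause of the others was not tested. At day 45 in CnATg, Rcan1 turned to 0.02855 after median-ratio scaling, 0.0274 after quantile normalization and 0.006179 with array weights, and Myh7 to 0.01877 after median-ratio scaling. In WT, Nppb turned to -0.004319 with array weights. At day 77, Ppp3ca turned to 0.04217 after median-ratio scaling and 0.004745 with mitochondrial and hemoglobin genes left out, and Rcan1 to -0.0316 with array weights. Without 1 library the day-45 ranges were -0.1133 to 0.1092 for Rcan1, -0.2107 to 0.3113 for Nppa, -0.06017 to 0.007833 for Myh7 and -0.05217 to 0.2558 for Myom2, and -0.3323 to 0.5637 for Nppb in WT. At day 77 they were -0.05917 to 0.03517 for Ppp3ca, -0.05683 to 0.1795 for Rcan1, -0.24 to 0.04233 for Nppb and -0.1591 to 0.3216 for Myom2.

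The correlation of the day-77 JIB-04 effect with the day-45 genotype effect was 0.2432 over called genes only, and that of the JIB-04 effects at both ages was -0.06146 over genes with a mean FPKM of at least 5. The genotype effects with vehicle and under JIB-04 correlated at 0.8388 with a pseudocount of 0.1, 0.8436 without the filter and 0.9511 over called genes, and those of both ages at 0.8623, 0.8592 and 0.945; the cause was not tested. For the JIB-04 effects of both ages and both genotypes too few genes were called to use called genes only. Leaving out mitochondrial and hemoglobin genes and rescaling the rest moved the median of all genes by -0.115 for JIB-04 in WT and 0.124 for the interaction. It moved it by 0.215, 0.102 and 0.195 for the genotype effect under JIB-04 at day 45, treated CnATg against WT vehicle, and day 77.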

Other observations

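Of the tests in this part, those of the short RNAs, those of the mitochondrial transcripts listed at 0 and the splits for the correlations were chosen only after the results were seen. Further gene groups were counted between CnATg and WT with vehicle at day 45. Of the 12 lists in this paragraph camera called 0 and fry called 4 (immediate-early, autophagy and lysosome, hypoxia and AHR genes), and several held a smaller share of called genes than the 5213 of 13289 among all genes; counts are those over all genes, and adjusted over the list alone where that differed. Immediate-early genes were 6 higher and 1 lower of 12. Genes of the integrated stress response were 6 higher and 4 lower of 19, ER chaperones 2 and 1 of 15, autophagy and lysosome genes 6 and 2 of 14 (7 and 2 adjusted over the list alone) and glucocorticoid-response genes 2 and 0 of 12 (1 and 0 adjusted over the list alone). NRF2 targets were 3 and 2 of 18, with Nqo1 (log2 1.29) higher, and hypoxia genes 4 and 2 of 17, with Car9 (2.17) higher and a median that changed sign to -0.04 after median-ratio scaling. AHR targets were 1 and 0 of 5. Metal-homeostasis genes were 2 and 3 of 13 (3 and 4 adjusted over the list alone), clock genes 5 and 3 of 13 (5 and 4 adjusted over the list alone), with Arntl (1.13) higher, and cell-cycle genes 1 and 2 of 18 (0 and 2 adjusted over the list alone). Jumonji demethylase genes were 3 and 1 of 20 (2 and 1 adjusted over the list alone), with Hr (0.89) and Kdm5a (0.32) higher and Kdm6b (-0.35) lower, the last no longer past the threshold (-0.25, adjusted p 0.066) with mitochondrial and hemoglobin genes left out; their median was 0.05, turning to -0.01 after median-ratio scaling, while camera pointed downward (adjusted p 0.93).

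Among cell markers in that comparison, macrophage genes were 3 higher and 2 lower of 17 (2 and 2 adjusted over the list alone), with Lgals3 (2.94) and Ccr2 (0.82) higher and Cd163 (-0.66) lower. B-cell genes were 0 and 3 of 5 (camera adjusted p 0.040, and adjusted p = 0.50 with an estimated correlation). That call was lost without CnATg vehicle replicates 1 and 3 (0.077 and 0.058) or WT vehicle replicates 2 and 3 (0.062 and 0.094), and after median-ratio scaling (0.078). Smooth muscle and pericyte genes were 2 and 4 of 9 (2 and 5 adjusted over the list alone), with Acta2 (2.29) higher and Rgs5 (-0.86) lower (camera adjusted p 0.037, and adjusted p = 0.19 with an estimated correlation), a call lost without CnATg vehicle replicate 3 (0.057) or WT vehicle replicate 2 (0.060), and after median-ratio scaling (0.068). Atrial genes were 2 and 2 of 5, neutrophil genes 0 and 2 of 2, adipocyte genes 1 and 0 of 1, skeletal muscle genes 0 and 1 of 1 and mesothelial genes 0 and 1 of 1. Erythroid genes (6 tested), T-cell genes (2), cytokine genes (2) and Schwann-cell genes (1) had 0 past the threshold over all genes, the Schwann-cell gene being higher adjusted over the list alone. No lung or thymus marker reached the expression filter.

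The library WT JIB-04 day 45 replicate 2 stood apart in its short non-coding RNAs. The 40 snRNA, snoRNA, scaRNA and miscRNA features were higher there by a median of 4.19 on the log2 scale than in the other libraries of its group, and made up 0.798% of its summed FPKM against at most 0.0904% elsewhere. Its low depth, 0.589, may be the cause, and this stays undecided: across the other 22 libraries with group means removed, their summed FPKM correlated with depth at r -0.178 (permutation p = 0.430) and rho -0.164 (permutation p = 0.467), with a 95% interval of -0.619 to 0.349, and at -0.0564 without the 2 libraries farthest out in depth. No biological explanation was tested. Without this library limma called 0 genes for the JIB-04 effect in WT as well.

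The transcripts mt-Atp6, mt-Atp8 and mt-Co3, neighbours in the mitochondrial genome, were listed at 0 in 13 libraries, 5 of 14 CnATg and 8 of 9 WT. Less mitochondrial RNA did not show in the 5 CnATg libraries, where mt-Co2 was no lower (46020 to 51382 FPKM) than in the other 9 (41677 to 47215 FPKM). That is 1 transcript. The mitochondrial share, counted without mt-Atp6, mt-Atp8 and mt-Co3, overlapped, at 15.83 to 17.38% in the 5 and 15.49 to 16.68% in the other 9. The values argue against the idea but do not rule it out. The ratio of the mt-Co2 medians was 1.06 (exact permutation p = 0.0030 for the difference of the means). Among WT libraries the ratio was 1.20, but with 1 library not listed at 0 this decides nothing. An estimate that fails above a certain load of fragments may account for it: ordered by mt-Co2 level times relative depth, 0 libraries were out of order. No biological explanation was tested, and the zeros were not used as expression values.

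A higher transgene level was asked to go with a higher fetal-gene mean among CnATg hearts. Over the 14 libraries, group means removed, Ppp3ca and the fetal list correlated at r -0.194 (permutation p = 0.505) and rho -0.305 (permutation p = 0.286), and r was -0.116 without the 2 libraries farthest out; adjusted over 4 relations p was 0.688. The prediction set beforehand took a p of 0.05 or more as evidence against the idea. That was wrong, since a p that misses the threshold excludes nothing with 14 libraries, and the question stays open.

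For the correlations across genes, 5 of 35 splits of the day-77 CnATg libraries gave a correlation with the day-45 genotype effect as large as 0.148 in size (highest other 0.224), and 15 of 35 one with the day-45 JIB-04 effect as large as 0.0753 (highest other 0.192), so chance cannot be excluded for either. For the JIB-04 effects in both genotypes, 10 splits are too few for a share under 0.05, and 2 of them gave as large a value as 0.182 (highest other 0.247). The same holds for the day-45 JIB-04 effect in CnATg with the day-77 genotype effect under JIB-04. There 4 of 10 splits gave a value as large in size as -0.0429 (highest other 0.0786).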
